A study of Homo sapiens with 12 samples.

How the data were processed

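RNA was extracted with TRIzol from MDA-MB-231 cells carrying guide RNAs, and total RNA libraries were made by standard Illumina protocols, per the labels' protocols, which do not state strand. The deposited count table holds whole-number read counts per gene for 12 libraries, and the deposited FPKM table holds FPKM values for the same libraries. Per the submitters' processing notes, fastp 0.20.1, STAR 2.7.7a and featureCounts 2.0.0 were used with GRCh38, and the role and settings of each are not given in the sources used here. All 58735 gene identifiers of the tables are in GENCODE release 29. The FPKM column totals relative to the count totals followed DESeq2-type (RLE) size factors (r = 1) and less closely TMM factors (r = 0.996).

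Libraries were put into 4 groups of 3 by the titles in the labels. Each FPKM column was multiplied by gene length and compared with each count column over 9901 genes. The SD of the log2 ratio was 2e-10 for the matching column and at least 0.129 for the next best. For 6 libraries the matching columns had the same name, and for 6 the names of the groups sgUFL1 and controls for sgUFM1 were exchanged. Comparisons were fixed under the names of the count table before the data were examined, and those under the names of the FPKM table, and of sgUFM1 with the controls for sgUFL1, were added after the exchange was seen. No group was assigned from measured values.

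Changed genes were tested on the counts in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with filterByExpr, TMM scaling and Benjamini-Hochberg adjustment at 0.05, with the 6 libraries of a comparison in each model and all 12 in the interaction. The standard error of a log2 fold change was derived from the same model. Replicates within a group differed by a chi-square per gene of 2.41 to 34.88, above sampling noise, so none was taken as a library deposited more than once. Named genes are the 8 highest and 8 lowest log2 fold changes among protein-coding genes past the threshold with a mean of at least 5 CPM in 1 group and no overlap between groups, 6 in each direction for the interaction, 5 in each direction for the control groups, 8 in each direction for genes shared by both guides, up to 4 members per list by smallest p, and UFL1 and UFM1.

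There were 31 gene lists fixed before the data were examined, covering ER stress, the ATF4 response, the UFMylation machinery, the ER translocon, ER-phagy, ribosomes and their biogenesis, oxidative phosphorylation, inflammation, interferon, antigen presentation, checkpoint ligands, the cell cycle, p53, histones, lipid synthesis, hypoxia, heat shock, NRF2, YAP, lysosomes, immediate early genes, matrix, epithelial and mesenchymal markers, and markers of luminal cells, leukocytes, and fibroblasts with endothelium. Of their symbols 855 were found directly, 55 through older names and 3 not at all. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation.

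GC content and length were obtained for 58676 genes from the reference. Offsets per library from a lowess trend (span 0.3) on GC content and length were added after a GC trend between libraries was seen. Other alternatives were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, a model over all 12 libraries, a replicate block, all 6 libraries named as controls pooled, each library left out in turn, fry in place of camera, and limma on log2(FPKM + 0.5) for genes of at least 0.5 FPKM in 3 libraries, with pseudocounts of 0.1 and 1. The result of 1 gene is not reported here, and the totals of alternative values include it.

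The procedure was tested on simulated data drawn from the real means and library sizes. Of genes changed 1.5-fold, 2-fold and 4-fold it recovered 13.4%, 55.2% and 86.4% for sgUFL1 under the count names (14709 genes), 35.8%, 67.2% and 87.9% under the FPKM names (14882 genes), 67.2%, 80.6% and 97% for sgUFM1 under the count names (14846 genes), 50.7%, 74.6% and 92.4% under the FPKM names (14740 genes) and 46.3%, 76.1% and 92.4% against the controls for sgUFL1 (14782 genes). False calls in the same order were 2 of 105, 10 of 137, 6 of 169, 6 of 151 and 10 of 153. Genes were drawn independently and without a GC trend, unlike the real libraries, so recovery and false calls there may differ. A simulated GC trend over 14868 genes gave 8201 calls without offsets and 19 with them. In that simulation 40 genes also carried a true shift, and how many of the 19 calls were among them was not recorded. Without stated strand, reads of overlapping antisense genes cannot be told apart, and short or GC-rich transcripts can shift with library preparation.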

Results

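Total RNA was sequenced from MDA-MB-231 cells, an established human breast cancer line of the triple-negative type, that carried a guide RNA against UFL1, a guide against UFM1 or a control guide. UFM1 is a small ubiquitin-like protein that is attached to other proteins, mainly at the endoplasmic reticulum (ER), and UFL1 is the ligase that attaches it. The labels give 4 groups of 3 libraries: sgUFL1, sgUFM1, and separate control libraries for each of the 2 guides. The title of the series speaks of knockdown and its design text of knockout. Totals over the 58735 genes of the count table ran from 15342793 to 18033331 counts per library. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

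The count table and the FPKM table of the series did not name the libraries alike. For 6 of the 12 libraries the FPKM column was proportional to the count column of the same name. For the other 6 it was proportional to the column of another group. The 3 libraries that the count table names sgUFL1 stand in the FPKM table as controls for sgUFM1, and are called set 1 here. The 3 libraries that the count table names controls for sgUFM1 stand in the FPKM table as sgUFL1, and are called set 2. The controls for sgUFL1 and the sgUFM1 libraries were named alike in both tables. Every comparison that involves set 1 or set 2 is therefore given under both namings. The comparison of sgUFM1 with the controls for sgUFL1 comes first, since it is the one that both tables name in the same way. By their titles these controls belong to the other guide, so differences in culture or library preparation cannot be told apart from the guide there. The mean GC content of the counted transcripts was 47.59% to 48.66% in these controls and 49.09% to 50.26% in all other libraries.

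UFL1 and UFM1 transcripts were measured in every library as a check of the names. UFL1 (ENSG00000014123, GRCh38 chromosome 6, 96521595 to 96555276) stood at 24.9 ± 5.25 CPM (counts scaled to equal library totals; mean ± SD, n = 3) in the controls for sgUFL1, 18 ± 1.27 in set 1, 12.5 ± 0.897 in set 2 and 23.1 ± 2.32 in the sgUFM1 libraries. The highest set 2 library had 13.2 CPM and the lowest of the 9 other libraries 16.7. Relative to the controls for sgUFL1, UFL1 had a log2 difference of -1.02 in set 2 (SE 0.17, adjusted p = 0.0017) and -0.45 in set 1 (SE 0.17, adjusted p = 0.13). UFL1 in set 1 lay above set 2 by 0.53 (SE 0.12, adjusted p = 0.052). Under the names of the count table UFL1 was thus not past the threshold in the libraries labelled sgUFL1 and was lowest in the libraries labelled as controls for sgUFM1. With offsets for GC content and gene length the set 2 difference was -0.49 (adjusted p = 0.04) and that of set 1 -0.1 (adjusted p = 0.89). Without controls for sgUFL1 replicate 3 the set 1 difference was -0.28 (adjusted p = 0.35). Relative to sgUFM1, UFL1 in set 2 had a log2 difference of -0.9 (SE 0.11, adjusted p = 5.6e-06), and of -0.65 with offsets (adjusted p = 1.8e-05). UFM1 (ENSG00000120686, chromosome 13, 38349849 to 38363619) stood at 65.6 ± 5.77, 53.5 ± 3.81, 53.9 ± 2.18 and 38.7 ± 1.35 CPM in the same order. The controls for sgUFL1, set 1 and set 2 lay above sgUFM1 by log2 differences of 0.76 (SE 0.11, adjusted p = 0.0026), 0.47 (SE 0.09, adjusted p = 0.01) and 0.47 (SE 0.08, adjusted p = 0.00012). With offsets those of the controls for sgUFL1 and of set 2 were 0.48 and 0.71, and the call against set 1 ended without sgUFM1 replicate 2 or 3. UFL1 overlaps the antisense gene UFL1-AS1, and the sources used here do not say whether counting used strand. A transcript that carries a frameshift can still be counted, so the transcript level does not measure the protein.

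**Figure D1:**
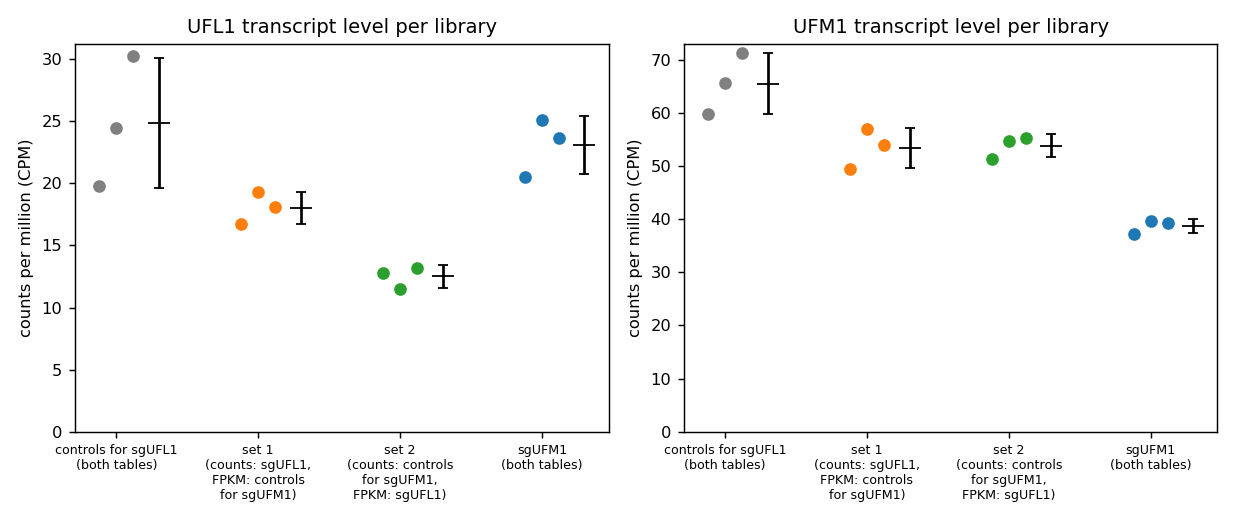
Transcript levels of UFL1 (left) and UFM1 (right) in CPM, one point per library, with the mean and SD of each set of 3 libraries as the black mark and bar. Set 2 is lowest for UFL1 (12.5 CPM on average) and sgUFM1 is lowest for UFM1 (38.7 CPM).

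In sgUFM1 against the controls for sgUFL1, MUC5AC, a gel-forming mucin, was higher by 2.84 log2 units (SE 0.14, adjusted p = 1.3e-07, 494 against 68.6 CPM). The trefoil peptides TFF2 and TFF3 were higher by 2.00 (SE 0.39) and 1.82 (SE 0.41), and the granulocyte growth factor CSF3 by 2.04 (SE 0.46). CSF3 stood at 97.9, 467 and 99.2 CPM in the 3 controls, and without replicate 2 of them its change was 3.21. The calls of CSF3 and TFF3 ended by DESeq2 (adjusted p = 0.067 and 0.057), without controls replicate 1 and without sgUFM1 replicate 1. The bradykinin receptor BDKRB2, the epithelial transcription factor EHF, the anchoring-fibril collagen COL7A1 and the adhesion receptor ADGRD1 were higher by 1.99 to 2.21. Lower genes included ESM1, an endothelial-type proteoglycan, which fell by 4.70 (SE 0.29, adjusted p = 2.4e-06; 1.47 against 38.3 CPM), and EPB41L3, a cytoskeletal adaptor of the protein 4.1 family, which fell by 3.79 (SE 0.13, adjusted p = 6.8e-09). PGM5, CNTN1, SUSD2, TMPRSS15, RELN and NAP1L3 had log2 changes from -3.86 to -2.81, and the call of PGM5 ended without controls replicate 1 (adjusted p = 0.053). Each of these genes was named on the condition that the sgUFM1 libraries did not overlap with the controls, so the absence of overlap adds no support. BDKRB2, COL7A1, ADGRD1, ESM1, PGM5, CNTN1, TMPRSS15 and RELN overlap other annotated genes on the same strand and EPB41L3 on the other, so part of their reads is uncertain. In all, 837 genes were higher and 666 lower of 15035 tested, 203 and 149 of them by at least 2-fold. These counts rest on few libraries: without controls for sgUFL1 replicate 1, 2 or 3 they were 369 and 281, 2195 and 2001, or 540 and 357. Without sgUFM1 replicate 1, 2 or 3 they were 165 and 110, 229 and 146, or 287 and 176. Fold changes followed GC content across genes (rho = 0.52, with genes not independent of one another), and offsets for GC and length left 649 higher and 601 lower, of which 846 were among the first 1503 with the same sign.

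Among the gene lists in this comparison, targets of the IRE1-XBP1 and ATF6 branches of the ER stress response had 7 of 39 members higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 0.00059, and adjusted p = 0.49 with an estimated correlation). The coat protein SEC24D of vesicles that leave the ER rose by 0.72 (SE 0.1), the ER-associated degradation factor SELENOS by 0.58 (SE 0.14), the secreted factor MYDGF by 0.51 (SE 0.14) and the transcription factor XBP1 by 0.45 (SE 0.11). NF-kB and inflammatory cytokine genes had 14 of 32 higher and 2 lower (18 and 4 adjusted over the list alone; camera adjusted p = 0.00013, and adjusted p = 0.51 with an estimated correlation). PTGS2, the inducible cyclooxygenase, was higher by 1.38 (SE 0.28) and IL11 by 1.01 (SE 0.18), while the chemokine CCL2 fell by 1.72 (SE 0.12). Of 18 genes for MHC class I presentation 5 were higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.51 with an estimated correlation). Among them were the immunoproteasome subunit PSMB10 (1.08, SE 0.28) and the peptide trimmer ERAP1 (0.44, SE 0.1). HLA-B and HLA-C, at 0.48 (SE 0.13) and 0.46 (SE 0.12), share reads with related HLA genes and are uncertain. With offsets for GC and length the calls of HLA-B, HLA-C, PSMB10 and MYDGF ended (adjusted p = 0.082, 0.41, 0.056 and 0.074). Those of SELENOS, MYDGF, XBP1, PSMB10, ERAP1, HLA-B, HLA-C and AGR2 ended without controls replicate 1 and without any 1 of the sgUFM1 libraries. PTGS2 and SPDEF lost theirs without controls replicate 1, and COL5A1 and TFF1 without sgUFM1 replicate 1. Markers of luminal breast cells, a cell type other than this basal-like line, had 5 of 16 higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0018, and adjusted p = 0.49 with an estimated correlation). TFF1 stood at 2.46 (SE 0.46), SPDEF at 1.59 (SE 0.29) and AGR2 at 0.92 (SE 0.21). The 13 mitochondrially encoded genes had 0 higher and 2 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.00026, and adjusted p = 0.49 with an estimated correlation). The mitochondrial share of counts was 4.51% to 4.76% in those controls, 3.42% to 3.89% in set 1, 3.68% to 4% in set 2 and 3.12% to 3.73% in sgUFM1. Those controls thus stood above all other sets. In sgUFM1 the mitochondrial list was not called against set 1 (camera adjusted p = 0.41) and was called lower against set 2 (camera adjusted p = 0.015). Extracellular matrix genes and proteases went both ways, with 11 of 31 higher and 3 lower (14 and 4 adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.51 with an estimated correlation). COL5A1 was higher by 0.68 (SE 0.13), and the collagenase MMP1 and the stromelysin MMP3 fell by 2.72 (SE 0.12) and 2.63 (SE 0.52). MMP3 had 14.5, 78.7 and 17.2 CPM in the 3 controls, and without replicate 2 of them its change was -1.41 (adjusted p = 5.5e-05). With offsets COL5A1 had 0.4. MMP1 and MMP3 overlap the antisense gene WTAPP1 and are uncertain without strand. Immediate early genes (6 higher and 2 lower of 24; 13 and 2 adjusted over the list alone), cytosolic ribosomal proteins (3 and 0 of 77; 0 and 0 adjusted over the list alone) and immune checkpoint ligands (2 and 0 of 8; 3 and 0 adjusted over the list alone) were called higher, with camera adjusted p of 0.0031, 0.027 and 0.027. So were mesenchymal markers (2 and 0 of 19; 4 and 1 adjusted over the list alone) and hypoxia genes (4 and 0 of 31; 4 and 1 adjusted over the list alone), with camera adjusted p of 0.043 and 0.046. These 5 lists had adjusted p = 0.49, 0.82, 0.49, 0.49 and 0.62 with an estimated correlation. The checkpoint list holds CD274, which lies in a stretch of chromosome 9, described below, that was higher in sgUFM1 and set 2. Its call may rest partly on that stretch, which was not tested. The hypoxia call ended with offsets for GC and length (camera adjusted p = 0.088), and the medians of luminal, immediate early and matrix genes went from 0.24, 0.34 and 0.34 to 0.15, 0.15 and 0.16. Markers of leukocytes and of fibroblasts and endothelium, as signs of other cells, were not called (camera adjusted p = 0.6 and 0.99).

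Which genes differed in sgUFM1 whatever the names of set 1 and set 2 was asked next, a comparison chosen after the disagreement of the names was seen. Under either naming set 1 or set 2 is the sgUFL1 set. Genes that both guides change to a like extent are therefore not counted here. Against each of the 3 other sets, 183 genes were higher and 119 lower of 14669 tested in all 3 comparisons, and 297 and 224 with offsets for GC and length. Leaving out sgUFM1 replicate 1, 2 or 3 gave 54 and 41, 35 and 25, or 48 and 33, and leaving out controls for sgUFL1 replicate 1 gave 106 and 82. Independent lists would share 7.7 and 6.2. ESM1 changed by -4.70 (SE 0.29), -4.20 (SE 0.28) and -4.49 (SE 0.15) against the controls for sgUFL1, set 1 and set 2. MUC5AC rose by 2.84 (SE 0.14), 2.33 (SE 0.12) and 2.68 (SE 0.13) in the same order, BDKRB2 by 2.21, 1.92 and 2.00, and EHF by 2.09, 1.87 and 2.39. RELN, a large secreted matrix glycoprotein, changed by -2.96, -2.52 and -2.99, and the chemokine receptor CXCR4 by -2.20, -1.85 and -2.01. The adhesion molecule PECAM1 and the cyclooxygenase PTGS2 were higher in all 3, by 1.46 to 1.78 and by 1.27 to 1.83. The ER export gene SEC24D had 99.8 ± 2.94 CPM in sgUFM1 (SD, n = 3) and 60.4 ± 3.48, 47.7 ± 2.9 and 47.8 ± 3.59 in the controls for sgUFL1, set 1 and set 2. The 3 comparisons share the same sgUFM1 libraries, so chance values of those libraries enter all 3, and part of the excess over independent lists may come from them. In 20 simulations of 12 libraries without any effect the highest count was 0 in either direction by edgeR, which does not measure what the shared libraries add where effects are present. The genes named in this paragraph were chosen after their values were seen.

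**Figure D2:**
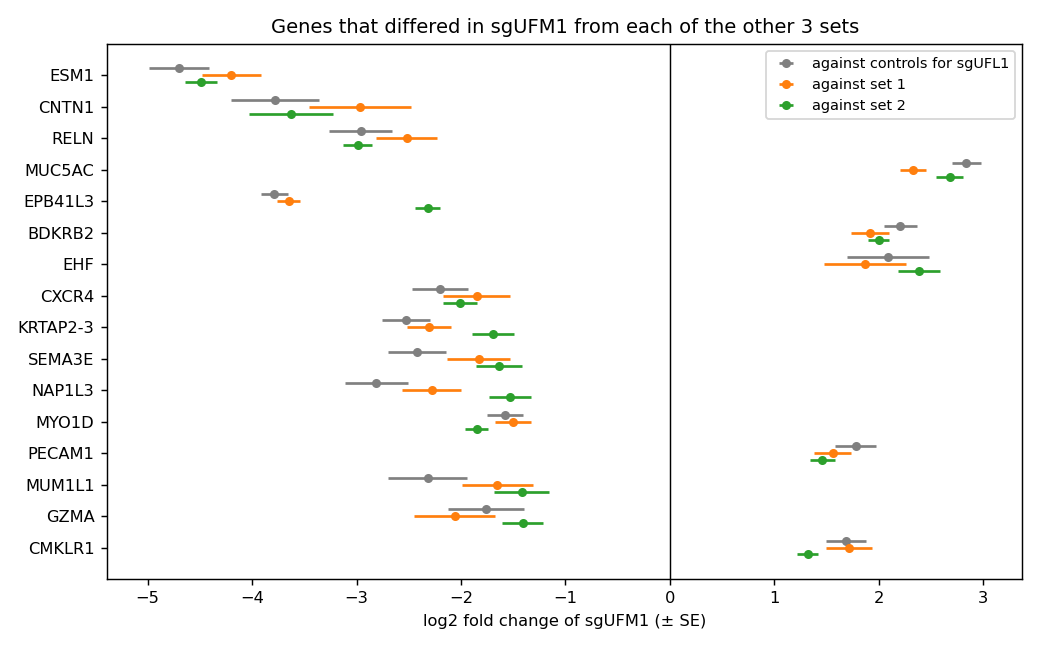
Log2 fold changes with standard errors of sgUFM1 against each of the 3 other sets for 16 genes past the threshold in all 3, ordered by the smallest of their absolute changes. ESM1 lies between -4.70 and -4.20 and MUC5AC between 2.33 and 2.84.

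Against its own controls as the count table names them (set 2), sgUFM1 had higher transcripts of the mucins MUC5AC by 2.68 (SE 0.13), MUC2 by 2.33 (SE 0.28) and MUC5B by 2.00 (SE 0.15). Also higher were the interferon-induced chemokine CXCL11 by 2.56 (SE 0.23) and the ER-resident disulfide isomerase AGR2 by 2.07 (SE 0.18), and the adjusted p of these 5 genes ran from 1.1e-11 to 3.3e-06. ESM1 fell by 4.49 (SE 0.15, adjusted p = 2.4e-14), and CNTN1, PGM5, RELN, TNS1 and ANO2 had changes of -3.63 to -2.61. Counts of changed genes were 2906 higher and 2791 lower of 15083, with 184 and 324 at least 2-fold. Under the names of the FPKM table this compares sgUFM1 with the libraries labelled sgUFL1. MUC5B, CXCL11 and ANO2 overlap annotated antisense genes and are uncertain without strand. With all 6 libraries that the count table names as controls pooled, 111 were higher and 94 lower, and in 1 fit over 12 libraries 1497 and 1526. Offsets for GC and length left 2456 and 2599, of which 3641 were among the first calls with the same sign.

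Lists in this comparison moved in both directions. ER stress genes had 27 of 39 higher and 2 lower (29 and 4 adjusted over the list alone; camera adjusted p = 2.1e-09, and adjusted p = 0.15 with an estimated correlation). SEC24D stood at 1.07 (SE 0.08), the lectin chaperone CANX at 0.62 (SE 0.06), EDEM3 at 0.74 (SE 0.07) and the ER chaperone HSP90B1 at 0.57 (SE 0.06). Genes of the ER translocon and signal recognition particle, where UFM1 is attached to ribosomes docked at the membrane, had 19 of 31 higher and 0 lower (21 and 0 adjusted over the list alone; camera adjusted p = 9.3e-08, and adjusted p = 0.42 with an estimated correlation). Members included SEC63 (0.78, SE 0.08), SSR1 (0.73, SE 0.07) and SEC61A1 (0.53, SE 0.06). NF-kB genes had 20 of 32 higher and 2 lower (21 and 2 adjusted over the list alone; camera adjusted p = 2.1e-09, and adjusted p = 0.22 with an estimated correlation). Type I interferon-stimulated genes had 25 of 48 higher and 2 lower (25 and 3 adjusted over the list alone; camera adjusted p = 4.6e-06, and adjusted p = 0.14 with an estimated correlation). Both lists were called with an estimated correlation once offsets for GC and length were used (NF-kB and interferon, adjusted p = 0.037 each), which held for no other list in any comparison. The antiviral gene IFIT1 rose by 1.46 (SE 0.09), OASL by 1.23 (SE 0.1), IL1B by 1.11 (SE 0.07) and the chemokine CXCL1 by 0.97 (SE 0.06). Cytosolic ribosomal proteins had 53 of 77 lower and 0 higher (55 and 0 adjusted over the list alone; camera adjusted p = 8.2e-15, and adjusted p = 0.46 with an estimated correlation), though many have near-identical pseudogenes. Nuclear-encoded oxidative phosphorylation genes had 29 of 49 lower and 0 higher (30 and 0 adjusted over the list alone; camera adjusted p = 1.2e-09, and adjusted p = 0.42 with an estimated correlation). RPL8 fell by 0.84 (SE 0.07) and the cytochrome subunit CYC1 fell by 0.81 (SE 0.07). Epithelial markers had 10 of 15 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00024, and adjusted p = 0.42 with an estimated correlation). The keratins KRT7 and KRT8 stood at -0.79 (SE 0.07) and -0.60 (SE 0.07). With offsets for GC and length the values were smaller for EDEM3 (0.48), SSR1 (0.47), RPL8 (-0.51), CYC1 (-0.44) and KRT7 (-0.52), and the epithelial median went from -0.37 to -0.23. Genes of G2 and mitosis (19 higher and 3 lower of 36; 21 and 3 adjusted over the list alone) were called higher (camera adjusted p = 0.0026). Replication-dependent histones (0 and 8 of 15; 0 and 8 adjusted over the list alone), YAP and TEAD targets (2 and 11 of 23; 2 and 11 adjusted over the list alone) and mitochondrially encoded genes (0 and 6 of 13; 0 and 7 adjusted over the list alone) were called lower, each with a camera adjusted p of 0.015. These 4 lists had adjusted p = 0.42, 0.46, 0.42 and 0.59 with an estimated correlation. Epithelial markers were not called in sgUFM1 against the controls for sgUFL1 (camera adjusted p = 0.11) or set 1 (camera adjusted p = 0.71). They were called higher in set 2 against the controls for sgUFL1 (camera adjusted p = 0.00033). Ribosomal proteins were called higher in sgUFM1 against those controls (camera adjusted p = 0.027) and lower against set 1 (camera adjusted p = 0.01).

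Against its controls as the FPKM table names them (set 1), sgUFM1 again had higher MUC5AC (2.33, SE 0.12), BDKRB2 (1.92, SE 0.18), EHF (1.87, SE 0.39) and AGR2 (1.54, SE 0.19). CMKLR1, a chemerin receptor (1.72, SE 0.22), and PECAM1 (1.56, SE 0.18) were higher too. ESM1 fell by 4.20 (SE 0.28), EPB41L3 fell by 3.65 (SE 0.11) and MMP1 fell by 2.54 (SE 0.09), from 6070 to 1040 CPM. The adjusted p of these 9 genes ran from 2.8e-08 to 0.015, and the call of EHF ended without any 1 of the sgUFM1 libraries. Counts were 685 higher and 771 lower of 14977, with 85 and 84 at least 2-fold, and 654 and 553 with offsets for GC and length. Under the names of the count table this compares sgUFM1 with the libraries labelled sgUFL1. Single libraries moved these counts: without set 1 replicate 1, 2 or 3 they were 1838 and 2242, 377 and 437, or 306 and 319. Without sgUFM1 replicate 1, 2 or 3 they were 343 and 437, 62 and 56, or 113 and 91.

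ER stress genes were higher here too, 11 of 39 with 1 lower (16 and 2 adjusted over the list alone; camera adjusted p = 1.6e-06, and adjusted p = 0.52 with an estimated correlation). SEC24D stood at 1.06 (SE 0.08), XBP1 at 0.52 (SE 0.07), the mannosidase-like EDEM1 at 0.50 (SE 0.08) and the disulfide isomerase ERP44 at 0.45 (SE 0.08). Translocon genes had 8 of 31 higher and 0 lower (13 and 0 adjusted over the list alone; camera adjusted p = 5.1e-06, and adjusted p = 0.69 with an estimated correlation). Oxidative phosphorylation genes had 12 of 49 lower and 0 higher (17 and 0 adjusted over the list alone; camera adjusted p = 5.1e-06, and adjusted p = 0.69 with an estimated correlation). Cholesterol synthesis genes had 6 of 26 lower and 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 0.0043, and adjusted p = 0.69 with an estimated correlation), including FDFT1 at -0.52 (SE 0.08) and the reductase DHCR7 at -0.48 (SE 0.08). Immune checkpoint ligands had 2 of 8 higher and 0 lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.52 with an estimated correlation). CD274, which encodes PD-L1, rose by 0.66 (SE 0.11). The calls of CD274 and ERP44 ended without sgUFM1 replicate 2 or 3, those of FDFT1 and DHCR7 without replicate 2 and that of EDEM1 without replicate 3. CD274 lies in a stretch of chromosome 9 that a scan after offsets picked because 21 neighbouring genes were higher in set 2 and sgUFM1 than in the other 6 libraries. The call of the checkpoint list may rest partly on that stretch, which was not tested. NF-kB genes (7 higher and 3 lower of 32; 12 and 5 adjusted over the list alone) and interferon-stimulated genes (3 and 0 of 48; 9 and 1 adjusted over the list alone) were called higher, with camera adjusted p of 0.028 and 0.0043. So were G2 and mitosis genes (4 and 1 of 36; 4 and 1 adjusted over the list alone) and mesenchymal markers (4 and 0 of 19; 4 and 0 adjusted over the list alone), with camera adjusted p of 0.028 and 0.025. These 4 lists had adjusted p = 0.73, 0.63, 0.69 and 0.52 with an estimated correlation. The call for G2 and mitosis ended with offsets for GC and length (camera adjusted p = 0.056), and the median of mesenchymal markers went from 0.25 to 0.15. Ribosome biogenesis genes (1 higher and 6 lower of 34; 1 and 8 adjusted over the list alone), cytosolic ribosomal proteins (0 and 8 of 77; 0 and 11 adjusted over the list alone) and NRF2 targets (1 and 4 of 23; 2 and 5 adjusted over the list alone) were called lower, with camera adjusted p of 0.0043, 0.01 and 0.033. These 3 lists had adjusted p = 0.73, 0.75 and 0.75 with an estimated correlation.

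Under the names of the count table, the libraries labelled sgUFL1 (set 1) were compared with the controls for sgUFL1. TAF10, a subunit of the general transcription factor TFIID, was higher by 2.19 (SE 0.24), GPS2, a corepressor subunit, by 2.11 (SE 0.29), the mitochondrial ribosomal protein MRPL12 by 2.00 (SE 0.23) and the gamma-secretase subunit PSENEN by 1.86 (SE 0.31), with adjusted p of 0.045 to 0.049. These genes and NUDT3, SRXN1, PDXP and TXNDC5, at 1.34 to 1.59, each overlap another annotated gene on the same strand, to which reads can be lost, and are uncertain. The 3 lower genes were ZNF512 (-0.67, SE 0.13), MT-ND4L (-0.65, SE 0.11) and SCOC (-0.53, SE 0.1). ZNF512 and MT-ND4L overlap other annotated genes on the same strand and SCOC on the other, so they are uncertain too. In all 162 genes were higher and 3 lower of 14996, 35 and 0 by at least 2-fold. Under the names of the FPKM table this is the comparison of the 2 control groups. Fold changes followed GC content (rho = 0.75 across genes), and with offsets for GC and length edgeR called 0 genes, with 1049 at an unadjusted p under 0.05 against 4205 without them. DESeq2 without offsets called 1301 higher and 580 lower, and edgeR with RLE in place of TMM scaling called 0. The counts turned on single libraries: without controls for sgUFL1 replicate 1, 2 or 3 they were 0 and 0, 1643 and 776, or 1 and 0. Without set 1 replicate 1, 2 or 3 they were 363 and 16, 0 and 0, or 0 and 0. Lists called higher were cytosolic ribosomal proteins (2 higher and 0 lower of 77; 11 and 0 adjusted over the list alone; camera adjusted p = 0.00026) and oxidative phosphorylation (2 and 0 of 49; 12 and 1 adjusted over the list alone; camera adjusted p = 0.023). So were immediate early genes (1 and 0 of 24; 4 and 0 adjusted over the list alone; camera adjusted p = 0.029) and extracellular matrix (0 and 0 of 31; 4 and 0 adjusted over the list alone; camera adjusted p = 0.032). Lists called lower were G2 and mitosis (0 and 0 of 36; 0 and 9 adjusted over the list alone; camera adjusted p = 0.015) and mitochondrially encoded genes (0 and 1 of 13; 0 and 2 adjusted over the list alone; camera adjusted p = 0.015). Each of these 6 lists had adjusted p = 0.87 with an estimated correlation. The calls for immediate early, extracellular matrix and G2 genes ended with offsets (camera adjusted p = 0.83, 0.12 and 0.074). ER stress genes had 1 of 39 higher and 0 lower (3 and 1 adjusted over the list alone) and were not called (camera adjusted p = 0.75).

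Under the names of the FPKM table, the libraries labelled sgUFL1 (set 2) against the controls for sgUFL1 had higher MRPL12 by 2.40 (SE 0.22), GPS2 by 2.37 (SE 0.25) and TAF10 by 2.17 (SE 0.22). The secreted protein gene VSTM2L was higher by 1.99 (SE 0.23) and RAMP1, a receptor accessory protein, by 1.95 (SE 0.21), and these 5 genes had adjusted p from 8.2e-05 to 0.00036. MRPL12, GPS2 and TAF10 were also higher in set 1 against the same controls, and are uncertain for the overlaps given there. Under either naming set 1 or set 2 is a control set, so these rises are not particular to libraries named sgUFL1. IGFN1 fell by 3.03 (SE 0.35), MMP3 fell by 2.53 (SE 0.51), the developmental transcription factor TBX3 fell by 2.31 (SE 0.27) and MMP1 fell by 1.99 (SE 0.11), with adjusted p from 1.3e-06 to 0.0032. Without controls replicate 2, which had 78.7 CPM of MMP3 against 14.5 and 17.2 in the other 2, the MMP3 change was -1.32. With offsets VSTM2L and RAMP1 had 1.15 and 1.09. Counts were 2641 higher and 2797 lower of 15175, with 521 and 179 at least 2-fold. Under the names of the count table this is the comparison of the 2 control groups, with the sign turned. Fold changes followed GC content (rho = 0.74 across genes), and offsets for GC and length left 749 higher and 619 lower, of which 911 were among the first 5438 with the same sign. Without set 2 replicate 2 or 3 the counts were 1378 and 1108, or 1487 and 1185.

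In this comparison cytosolic ribosomal proteins had 40 of 77 higher and 0 lower (42 and 0 adjusted over the list alone; camera adjusted p = 9.5e-10, and adjusted p = 0.68 with an estimated correlation). Oxidative phosphorylation genes had 22 of 49 higher and 1 lower (23 and 2 adjusted over the list alone; camera adjusted p = 0.00058, and adjusted p = 0.68 with an estimated correlation). Examples were RPS21 (0.96, SE 0.12) and COX8A (1.29, SE 0.17). Epithelial markers had 8 of 15 higher and 0 lower (8 and 0 adjusted over the list alone; camera adjusted p = 0.00033, and adjusted p = 0.66 with an estimated correlation). The tight junction gene CLDN7 stood at 1.21 (SE 0.17) and KRT19 at 0.76 (SE 0.11). Immediate early genes had 10 of 24 higher and 0 lower (10 and 1 adjusted over the list alone; camera adjusted p = 0.00058, and adjusted p = 0.68 with an estimated correlation). JUN stood at 0.80 (SE 0.12) and EGR1 at 0.87 (SE 0.17). Lower lists were G2 and mitosis (1 higher and 15 lower of 36; 2 and 18 adjusted over the list alone; camera adjusted p = 0.0034) and the ER translocon (1 and 13 of 31; 1 and 14 adjusted over the list alone; camera adjusted p = 0.028). MHC class I genes were higher (8 and 1 of 18; 8 and 1 adjusted over the list alone; camera adjusted p = 0.029). These 3 lists had adjusted p = 0.68 with an estimated correlation. With offsets for GC and length the calls for immediate early, translocon and MHC class I genes ended (camera adjusted p = 0.17, 0.42 and 0.27), as did that of KRT19 (0.14, adjusted p = 0.47). The values for RPS21, COX8A, CLDN7 and JUN fell to 0.52, 0.78, 0.69 and 0.46, and the epithelial and G2 medians went from 0.57 to 0.27 and from -0.25 to -0.15. The mean GC content of the counted transcripts was 47.59% to 48.66% in the controls for sgUFL1 and 49.72% to 50.26% in set 2.

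**Figure D3:**
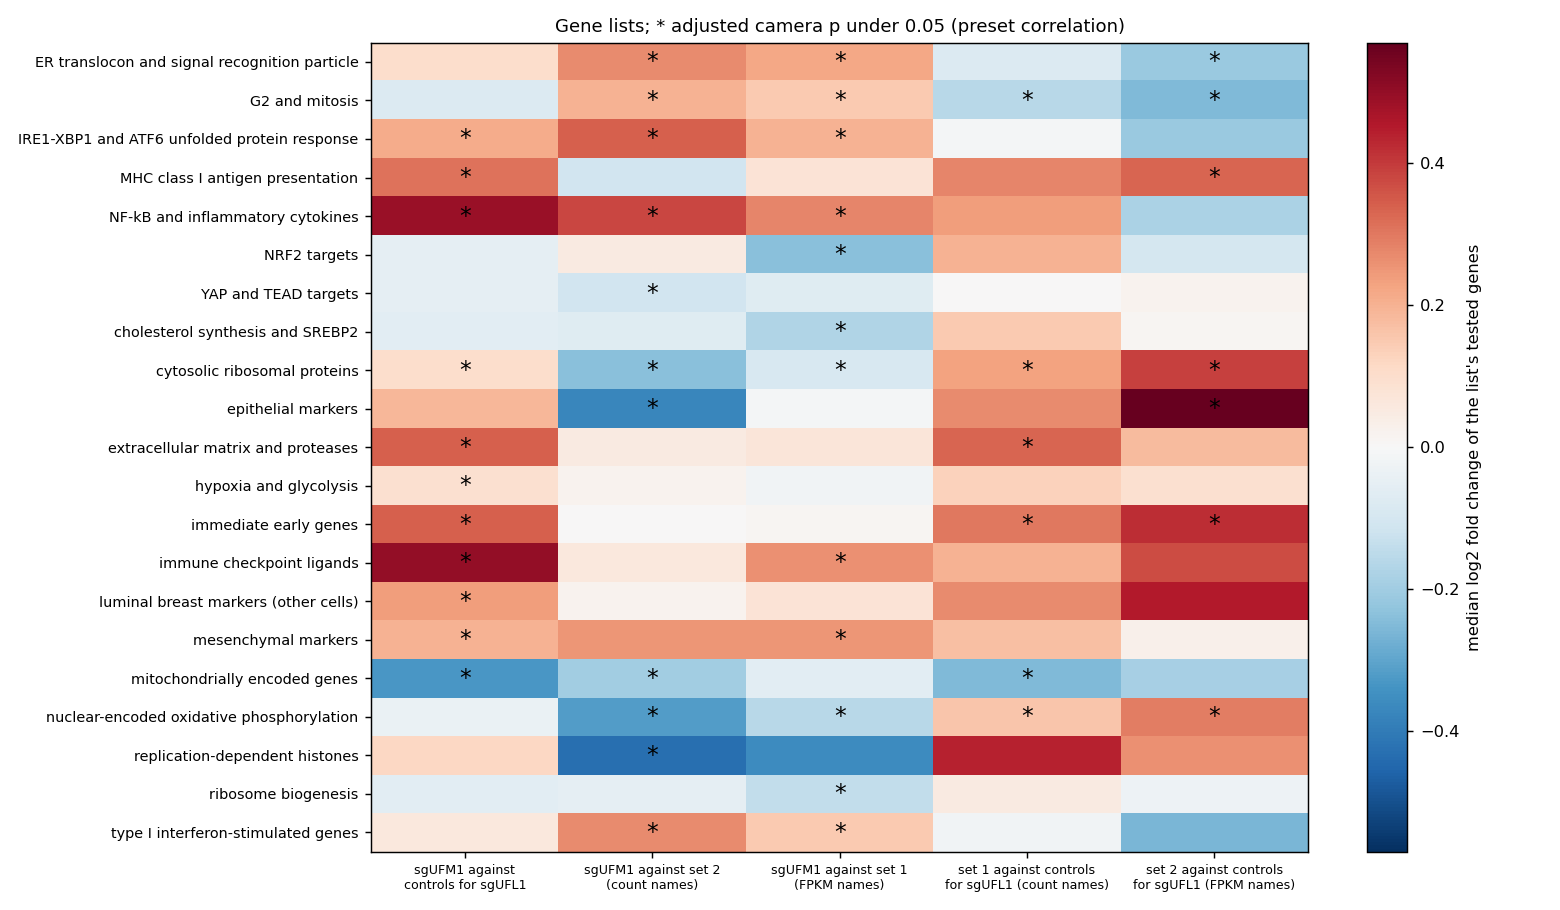
Median log2 fold change of each gene list, listed down the side, in the comparisons named along the bottom, for lists called in at least 1 of them, where an asterisk marks an adjusted camera p under 0.05 with the preset correlation. ER stress genes have medians of 0.21, 0.34 and 0.20 in the 3 sgUFM1 comparisons, with 7, 27 and 11 of 39 members higher past the threshold and adjusted p = 0.49, 0.15 and 0.52 with an estimated correlation. Ribosomal proteins turn direction between them.

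UFL1 and UFM1 act in one pathway, so the genes changed in the same direction by both guides were counted. With the count names 0 genes were higher in both by edgeR and 0 lower in both, where independent lists would share 31.9 and 0.6, and 130 genes were called in opposite directions. With offsets for GC and length 0 genes went in opposite directions, as edgeR then called 0 genes in sgUFL1. For opposite directions no value for independent lists was computed under either naming. At an unadjusted p under 0.05 in both, 116 genes were higher and 68 lower, and by DESeq2 with adjustment 40 and 12. Without controls for sgUFL1 replicate 2 edgeR gave 117 and 53, without set 1 replicate 1 it gave 13 and 2, and without sgUFM1 replicate 3 it gave 1 and 0. With the FPKM names 83 genes were higher and 77 lower in both, where independent lists would share 120.3 and 145.5, and 602 went in opposite directions. With offsets for GC and length the FPKM names gave 59 higher and 71 lower against 32.5 and 23 for independent lists, and 89 opposite. Single libraries moved the shared counts under the FPKM names. Without set 2 replicate 2 or 3 they were 51 and 45 or 52 and 49, without set 1 replicate 1 they were 169 and 161, and without set 1 replicate 2 the higher count was 52. Without sgUFM1 replicate 1, 2 or 3 they were 32 and 37, 16 and 14, or 24 and 21. Under these names the lower shared genes included MMP3 (-2.53 and -2.94 in sgUFL1 and sgUFM1), MMP1 (-1.99 and -2.54), the adaptor SAMSN1 (-1.99 and -2.22) and CCL2 (-1.40 and -1.55). The MMP3 value in sgUFL1 was -1.32 without controls replicate 2, and its call in sgUFM1 ended without any 1 of the sgUFM1 libraries. Higher ones included ARHGAP30 (1.47 and 1.18), the mucin-like FCGBP (1.01 and 0.98), the water channel AQP3 (1.00 and 0.96) and EGR1 (0.87 and 0.87). With offsets FCGBP in sgUFL1 had 0.48 and lost its call (adjusted p = 0.096), and AQP3 had 0.62. The log2 fold changes of both guides correlated at r = -0.29 across 14639 genes under the count names (rho = -0.40), and at r = 0 with offsets. Under the FPKM names r was -0.07 across 14719 genes (rho = -0.23), and r was 0.14 with offsets. Re-split libraries gave a median absolute r of 0.09 under the count names and 0.11 under the FPKM names, with highest values of 0.29 and 0.42 over 81 re-splits each. The real values on the same log2 CPM scale, -0.26 and -0.06, did not lie outside these.

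Whether the effect of the UFL1 guide differs from that of the UFM1 guide was tested as an interaction over all 12 libraries, whose contrast is the same under both namings. UFL1 itself had a lower effect in sgUFL1 than in sgUFM1, by -1.35 (SE 0.21, adjusted p = 0.00038), and by -0.76 with offsets. UFM1 did not differ past the threshold (0.18, SE 0.13, adjusted p = 0.3), though with offsets for GC and length it did (0.77, adjusted p = 0.0011). ESM1 (4, SE 0.41) and the neuronal adhesion gene CNTN1 (2.83, SE 0.65) had higher effects. AGR2 (-2.68, SE 0.3), MUC5AC (-2.16, SE 0.22), EHF (-2.16, SE 0.71), the unconventional myosin MYO16 (-2.15, SE 0.31) and the RNA sensor TLR3 (-1.79, SE 0.26) had lower ones. The call of EHF ended with offsets for GC and length (-1.84, adjusted p = 0.13), by DESeq2 (adjusted p = 0.052) and without controls for sgUFL1 replicate 2 (-1.23, adjusted p = 0.12). Of 15821 genes 2828 had a higher and 2683 a lower effect in sgUFL1, and with offsets for GC and length 863 and 609. Ribosomal protein genes (39 higher and 0 lower of 77; 41 and 0 adjusted over the list alone) and oxidative phosphorylation genes (22 and 0 of 49; 22 and 1 adjusted over the list alone) had higher effects, with camera adjusted p of 3.3e-09 and 2.2e-06. ER stress genes (4 and 18 of 39; 4 and 19 adjusted over the list alone) and translocon genes (1 and 14 of 31; 2 and 16 adjusted over the list alone) had lower ones, with camera adjusted p of 0.00055 and 0.00013. These 4 lists had adjusted p = 0.79, 0.70, 0.62 and 0.70 with an estimated correlation. With offsets the ER stress and translocon medians went from -0.32 to -0.21 and from -0.39 to -0.23.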

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

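The splits of the libraries for sgUFM1 under the FPKM names and against the controls for sgUFL1, the tests of the names, and the GC and length tests were chosen only after the results were seen. A difference between the effects of both guides, tested as an interaction in edgeR, brought up each result here: 2828 genes had a higher and 2683 a lower effect in sgUFL1 than in sgUFM1. The log2 differences were 4 for ESM1, 3.30 for MRPL12, 3.04 for GPS2, 2.86 for TAF10, 2.83 for CNTN1, -2.68 for AGR2, -2.16 for MUC5AC, -2.16 for EHF, -2.15 for MYO16, -1.79 for TLR3 and -1.35 for UFL1. XAGE1A had 5.09, which rests on set 1 replicate 1 (22.8 CPM, against 1.11 and 0.582 in the other libraries of the set), and its near-identical copy XAGE1B makes it uncertain. POTEC, which has near-identical copies, had -1.88. MRPL12, GPS2 and TAF10 overlap other annotated genes on the same strand, as do ESM1 and CNTN1, so part of their reads is uncertain. MRPL12, GPS2 and TAF10 were higher in both set 1 and set 2 than in the controls for sgUFL1. Their differences may thus rest on low values in those controls. Median differences of the lists were 0.48 for cytosolic ribosomal proteins, 0.42 for oxidative phosphorylation, 0.79 for epithelial markers, -0.39 for the ER translocon, -0.32 for ER stress, -0.37 for G2 and mitosis, and -0.41 for interferon-stimulated genes. With offsets for GC and length the epithelial median was 0.27, the translocon -0.23, ER stress -0.21 and G2 -0.22, all still called. With an estimated correlation none of the 7 lists was called, with adjusted p of 0.44 for epithelial markers, 0.62 for G2, interferon and ER stress, 0.70 for oxidative phosphorylation and the translocon, and 0.79 for ribosomal proteins. Of 100 drawn splits within both sets of 6 libraries, 1, the real one, gave as many genes (5511, against 2180 in the highest other). This argues against a chance assignment of these libraries to the groups. It cannot exclude chance differences between cultures, because the libraries of a group may be technical and the other splits mix groups that differ. A GC and length trend between libraries as the whole cause is argued against by the 1021 genes that stayed past the threshold in the same direction after offsets, though it may account for part of the other calls. The median of the called differences, measured in the direction first called, went from 0.74 to 0.25 with offsets. Whether the rest reflects the guides stays open, because the contrast also holds any difference between the sets in culture or library preparation, which was not tested.

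Set 1 and set 2 carry exchanged names in the count and FPKM tables. If the count table exchanged the names, UFL1 would be lower in set 2 than in the controls for sgUFL1, and it was, by a log2 change of -1.02, with each set 2 library below the 9 others. If the FPKM table exchanged them, UFL1 would be lower in set 1, where the change was -0.45 and did not pass the threshold, which does not exclude it. That value was -0.28 without controls for sgUFL1 replicate 3 and -0.1 with offsets for GC and length (adjusted p = 0.89). The UFL1 transcript is thus consistent with exchanged names in the count table, as a hypothesis found and tested on the same libraries, and with the same offsets the set 2 change was -0.49. Relative to sgUFM1, UFL1 in set 2 had a log2 difference of -0.9 by edgeR (adjusted p = 5.6e-06), and of -0.65 with offsets (adjusted p = 1.8e-05). A run of chromosome 9 genes, described below, was higher in set 2 and sgUFM1 than in set 1 and the controls for sgUFL1. Under the count names these pairs are each a guide with its own controls, and under the FPKM names both guides against both control groups. Under the FPKM names the 2 control groups are the controls for sgUFL1 and set 1, which differed in 165 genes, and in 0 with offsets. Under the count names they are the controls for sgUFL1 and set 2, which differed in 5438 genes, and in 1368 with offsets. Control groups may differ in culture or library preparation, so these counts do not settle the names. No library was moved to another group on these grounds.

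Genes called in sgUFL1 under the count names had a median GC content of 64.6%, against 47.9% for the genes tested. After offsets 0 of the 165 stayed past the threshold in edgeR. Their median change, measured in the direction first called, went from 0.76 to 0.21 and the median SE from 0.14 to 0.1. The calls thus ended because the changes shrank, and a GC and length trend could be the whole cause. Under the FPKM names 911 of 5438 genes (16.8%) stayed, and in sgUFM1 against the controls for sgUFL1 846 of 1503 (56.3%), which argues against that trend as the whole cause there. The median of the called changes, measured in the direction first called, went from 0.6 to 0.19 under the FPKM names and from 0.66 to 0.48 in sgUFM1. The trend may thus account for much of the changes under the FPKM names. The trend and a change in GC-rich transcripts brought by the guide were not separated further.

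With 6 libraries there are 10 splits, too few for a share under 0.05. For sgUFL1 under the count names 2 splits gave at least the 165 genes of the real one, and the other gave 1019. That split set controls for sgUFL1 replicates 1 and 3 with set 1 replicate 1 against the remaining 3, which points to a structure of the samples. For sgUFM1 under the count names (5697), the 2 control groups (5438), sgUFM1 under the FPKM names (1456) and sgUFM1 against the controls for sgUFL1 (1503), 1 split, the real one, gave as many, and the highest other gave 0.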

How the results depend on the processing

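The names of the FPKM table, the offsets for GC and length, FPKM values under the count names, and every alternative of the comparisons under the FPKM names and against the controls for sgUFL1 were chosen after the data were seen, and the other alternatives before. With 3 libraries per group, leaving out a library moved the counts of changed genes by more than 1.5 times in every comparison named here except sgUFM1 under the count names and the interaction. The cause was not tested for any value below. Counts are given as higher and lower.
For sgUFL1 under the count names (162 and 3), no filter gave 1508 and 413, the strict filter 296 and 10, RLE scaling 0 and 0, upper-quartile scaling 11 and 1, DESeq2 1301 and 580, the 12-library model 1992 and 1471, offsets 0 and 0, and pooled controls 0 and 0. The FPKM table under its own names gave 2347 and 2094 with a pseudocount of 0.5, 2296 and 2093 with 0.1, 2380 and 2104 with 1, and 997 and 790 without filter, and its values under the count names 0 and 0. The FPKM names gave 2641 and 2797, and with offsets 749 and 619. Leaving out a library gave 0 to 1643 and 0 to 776.
For sgUFM1 under the count names (2906 and 2791), the 12-library model gave 1497 and 1526, pooled controls 111 and 94, and the FPKM table under its own names, where values and naming change together, 371 and 426, 357 and 411 with a pseudocount of 0.1, 375 and 429 with 1, and 90 and 103 without filter. FPKM values under the count names gave 2182 and 2237. The FPKM names gave 685 and 771, and with offsets 654 and 553. Under the FPKM names the 12-library model gave 440 and 461, pooled controls 167 and 117, and leaving out a library 62 to 1838 and 56 to 2242. Against the controls for sgUFL1 (837 and 666), no filter gave 1300 and 1015, the 12-library model 1348 and 1217, and leaving out a library 165 to 2195 and 110 to 2001.
Between the 2 control groups of the count table, 2641 genes were lower and 2797 higher in the controls for sgUFL1. With offsets these were 749 and 619, and leaving out a library gave 1378 to 3430 and 1108 to 3555. The interaction (2828 and 2683) gave 863 and 609 with offsets.
Genes shared by both guides under the count names (0 and 0) were 88 and 29 without filter, 6 higher with the strict filter, 40 and 12 by DESeq2, 21 and 21 in the 12-library model, 83 and 77 under the FPKM names, and 0 to 117 and 0 to 53 with a library left out. Under the FPKM names no filter gave 117 lower, a 2-fold minimum 13 and 26, and leaving out a library 16 to 169 and 14 to 161. The correlation of -0.29 was -0.45 for genes of at least 5 CPM, -0.40 as Spearman rho, 0 with offsets, -0.07 under the FPKM names, and -0.33 to -0.17 with a library left out. The FPKM-named value of -0.07 was -0.25, -0.23 and, reversed, 0.14 with offsets, and -0.14 to -0.01 with a library left out.
Whether replicate numbers pair the libraries stays unclear for sgUFL1 under the count names, where same-numbered deviations correlated at 0.43, 0.44 and -0.24. In the other comparisons these correlations were low, at -0.09 to 0.16. The replicate block gave 0 and 0 for sgUFL1 under the count names, and 500 lower for sgUFM1 under the FPKM names.
Signs reversed with offsets for UFM1 in sgUFL1 (0.07, and 0.23 under the FPKM names), UFL1 in sgUFM1 against the controls for sgUFL1 (0.16, and 0.06 without those controls' replicate 3), EIF4EBP1 in sgUFM1 (0.05), and under the FPKM names in sgUFL1 for SEC62 (0.18), RTN3 (0.03), FASN (-0.17), SDF2L1 (-0.01), HLA-C (-0.07) and BCL3 (-0.07).
Of 564 alternative tests of 47 list calls, 436 kept the call and 128 lost it. Of these, 47 were lost with an estimated correlation, 32 with fry as a directional test and 4 with fry for changes in either direction. In sgUFM1 against the controls for sgUFL1 the lowest adjusted p of directional fry among the called lists was 0.054. Of 6106 alternative values of 498 named results, 5193 kept direction and call, 888 lost the call, 12 gained it and 13 reversed.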

Other observations

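Every test in this part was chosen after the result was seen except, under the count names, the arm test as first fitted and the gene lists without offsets. The lists for the UFMylation machinery (9 genes), the ATF4 branch of the integrated stress response (37 genes) and ER-phagy receptors (11 genes) were not called in any comparison without offsets. In sgUFM1 against the controls for sgUFL1 the ATF4 list had 4 genes higher and 1 lower (camera adjusted p = 0.58), and the UFMylation list 0 higher and 1 lower (camera adjusted p = 0.63), the lower one being UFM1. The lists for p53 targets, S phase and E2F, lysosome and autophagy, heat shock, and fatty acid synthesis were also not called in any comparison without offsets. In sgUFM1 against the controls for sgUFL1 their genes higher and lower were 2 and 1 of 25 for p53 targets (camera adjusted p = 0.58), 0 and 0 of 36 for S phase (0.54), 2 and 1 of 39 for lysosome (0.95), 3 and 1 of 18 for heat shock (0.54), 2 and 1 of 17 for fatty acid synthesis (0.63), and 1 and 0 of 11 for ER-phagy (0.63). With offsets and the preset correlation, S phase was called lower in sgUFL1 under the FPKM names (1.5e-05) and in the interaction (0.013), and higher in sgUFM1 under the count names (0.0015), and fatty acid synthesis lower in the interaction (0.046). The ATF4 list was called lower in sgUFL1 under the count names (0.006) and in the interaction (0.00063), and higher in sgUFM1 under the FPKM names (0.011) and the count names (0.026). With offsets and an estimated correlation the S phase values were 0.55, 0.58 and 0.17, that of fatty acid synthesis 0.19, and those of ATF4 0.92, 0.52, 0.59 and 0.3. Offsets gave 16 further calls to lists that are called elsewhere in the report, and with an estimated correlation none of these was called. Among them were translocon genes, higher in sgUFM1 against the controls for sgUFL1 (0.00011), and NF-kB genes, lower in the interaction (9.7e-05). KISS1, a secreted peptide precursor, changed by -1.07, -1.65 and -1.38 in sgUFM1 against the controls for sgUFL1, set 1 and set 2, and the phosphatase DUSP1 by -1.05, -1.15 and -1.47. The morphogen SHH was higher by 1.79, 1.09 and 1.09, and the lipid exporter ABCG1 by 1.65, 1.46 and 1.05. The chemokine receptor CXCR4 had 17.1, 13.4 and 15.1 CPM in the other 3 sets and 3.73 in sgUFM1.

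In a scan of 10765 genes along the chromosomes on values after offsets, 21 neighbouring genes from GLIS3 to PSIP1 (chromosome 9, 3824127 to 15511019, GRCh38) were higher in both set 2 and sgUFM1 than in the other 6 libraries, and the next longest run had 6 genes. The median of the run lay between 0.42 and 0.55 in set 2 libraries, 0.44 and 0.5 in sgUFM1, -0.11 and 0.1 in the controls for sgUFL1, and -0.08 and 0.15 in set 1. The region holds CD274, PDCD1LG2 and JAK2. Of 7 genes of the region left out of the scan 6 were higher in both, with a median of 0.65, above 99.9% of random sets. More copies of the region in those cells may account for this, a hypothesis that RNA alone does not settle. The 21 genes had a median of 0.4 before offsets and 0.48 after. A scan before offsets found 2 runs in the stretch, 6 genes from CDC37L1 to CD274 and 5 from KDM4C to NFIB. Their 11 genes went from a median of 0.44 to 0.57 with offsets (95% interval 0.47 to 0.61), all past the cut of the scan, which argues against a GC and length trend as the whole cause for them. For the other 10 genes this stays open, since they were chosen on values after offsets, and the longest run before offsets was another one, 14 lower genes from IMPA1 to NBN on chromosome 8 (-0.22 after offsets). The run groups set 2 with sgUFM1, which are control and guide under the count names and the 2 guides under the FPKM names.

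Loss of the chromosome arm beyond the guide's target would lower the genes distal to it. The bound set before the data were examined was a distal median more than 0.2 below the proximal one. For UFL1 the difference was -0.18 (95% interval -0.25 to -0.12) under the count names and -0.35 (-0.45 to -0.27) under the FPKM names, so the second met that bound. After offsets for GC and length, a test added once that value was seen, the differences were 0.03 (-0.01 to 0.06) and -0.06 (-0.1 to -0.01), which argues against a loss of that size, with the reservation that the offsets were chosen later. For UFM1 the differences were 0.09 and 0.14 after offsets under the count names, and 0.04 and 0.05 under the FPKM names, which argues against loss of that arm in most cells.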
